A study of Arachis hypogaea with 27 samples.

How the data were processed

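RNA was measured in roots of peanut (Arachis hypogaea). The 27 samples came from 3 genotypes: the cultivar Fleur11 and 2 chromosome segment substitution lines, 12CS_051 and 12CS_044. Substitution lines carry donor chromosome segments in the background of a recurrent parent, here Fleur11. Per the labels' protocols, plants grew at 28 °C with 16 h of light, without nitrogen, and inoculated plants received 1 ml of a Bradyrhizobium vignae strain. Samples at 0 days post-inoculation (dpi) were labelled as controls, with roots lacking nodules. Samples at 12 and 21 dpi were described as nodulated roots for every genotype. Total RNA was turned into stranded mRNA libraries, per the labels' protocols.

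The deposited table held 1 column of estimated counts per library, which the authors made with Salmon, per the submitters' processing notes. Those notes also name FastQC, cutadapt and STAR, without versions, settings or order. Over all 67124 genes, zeros included, 54.6% to 71.1% of the values in a library lay more than 0.001 from a whole number (83.3% to 90.0% of the values above 0), so the estimated counts were rounded before any test. The gene IDs belong to annotation 1 of genome version 1 of the cultivar Tifrunner, per the IDs themselves. Of the 67124 IDs, 0 matched the RefSeq table used for names, which follows version 2 of that genome, so IDs are given as deposited and carry no gene name, function or position here. No row lacked a gene ID.

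Groups were taken from the labels as genotype by day, which gave 9 groups of 3 libraries. Of the 27 columns, 17 could be tied to 1 sample by name and 10 only to a group, so replicate numbers are those in the deposited table. Nothing in the labels says whether the replicates of a group came from separate plants, so p-values measure the spread between these samples, which may be partly technical. Replicates of a group differed by more than sampling noise in every pair (chi-square per gene 12.6 to 426), which repeat preparations of the same sample could also show. All were counted as separate samples, as the labels list them. Total counts ran from 19.9 to 65.5 M per library (M, mega), and 43537 to 52973 genes had at least 1 count.

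The test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with limma 3.58.1. The default filter filterByExpr (minimum count 10) left 43848 genes, which held 99.9% of all counts, and TMM factors scaled the libraries. A single model with 9 group means and no covariate was fitted to all 27 libraries, which leaves 18 residual degrees of freedom and a shared estimate of the spread. Its common biological coefficient of variation was 42.9%. A gene was called where its Benjamini-Hochberg adjusted p lay below 0.05 within a comparison. Each line was compared with Fleur11 at each day, each genotype across days, the changes over time of each line with those of Fleur11 (interaction), and the lines with each other. Comparisons of 21 with 0 dpi were added after the data were seen. Levels are CPM values, counts scaled to the library total, given as mean ± SD with n = 3.

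Where all 3 libraries of a group had 0 counts, a fold is given as a lower bound against 3 counts over the pooled counts of the group. With over 3 counts, the ratio of pooled counts is given with its exact 95% binomial interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

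The rule for named genes was set before the data were examined. It took called genes whose libraries did not overlap between the groups and whose higher group had a mean of at least 5 CPM, ranked by fold change. Its condition on an informative gene name could not be applied, and it then allowed at most 2 rising and 2 falling IDs per comparison. For the lines over time it asked for the Fleur11 genes in the text; IDs ranked in those comparisons are in the tables and in the totals of ranked IDs and entries, but not in the text. For interactions it required no separation of libraries. Of the IDs it picked, those given for a comparison are ones that stayed called when any single library of the compared groups was left out, a restriction added after the data were seen. Of the 66 IDs that the ranking picked over all comparisons, 36 had almost no counts in 1 group and over 20 CPM in every library of another, a pattern for which reads shared between near-identical gene copies stay open in the closing section.

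An induced set was defined after the data were seen: genes below 0.5 CPM in every library at 0 dpi and at least 20 CPM in every Fleur11 library at 21 dpi. Its selection on Fleur11 favours a higher level in Fleur11, so the set was also defined in 12CS_051. Levels of the set were compared with a two-sided exact permutation test of log2 summed CPM, which cannot give a p below 0.1 for 3 against 3 libraries.

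The counts shared by both lines use the same Fleur11 libraries as controls. Groups without any difference were therefore simulated 10 times per day from the Fleur11 means and the fitted spread, and the overlap of independent lists was computed per direction. The procedure was tested on simulated data for 12CS_051 against Fleur11 at 21 dpi with 43848 genes. It recovered 36 of 100 genes changed 2-fold and 77 of 100 changed 4-fold, with 4 false calls among 43648 unchanged genes. That low number does not carry over to 12 dpi. There the simulated groups without any difference gave medians of 182.5 (12CS_051) and 187 (12CS_044) called genes, all false.

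Alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, a fit on the compared libraries alone, a minimum absolute log2 fold change of 1, and leaving out each library in turn. Leaving out Fleur11 at 12 dpi replicate 1 from comparisons that do not include its group was added after the data were seen. Tests of gene lists for nodulation, nitrogen and related functions, and a scan for clusters of changed genes along chromosomes, were not run because names and positions of these gene IDs were not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.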

Results

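Root RNA was profiled in 27 libraries of peanut to compare 2 chromosome segment substitution lines, 12CS_051 and 12CS_044, with their recurrent parent Fleur11. The series concerns genetic factors behind weaker nitrogen fixation by root nodules in lines with wild ancestry. Each genotype was sampled as a control at 0 dpi (days post-inoculation) and with nodulated roots at 12 and 21 dpi, with 3 libraries per group. Total counts ranged from 19.9 M (12CS_051 at 12 dpi replicate 2) to 65.5 M (Fleur11 at 12 dpi replicate 3). Of 67124 genes, 43848 were tested. Gene IDs were not paired with names here, so genes are described by level and direction.

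The first principal component held 21.1% of the variance and did not order the libraries as a whole by day or genotype. In 12CS_051 alone it fell with the day, from 112 to 120 (0 dpi) over 58.5 to 76.9 (12 dpi) to 18.5 to 41.7 (21 dpi). In 12CS_044 the component was lowest at 12 dpi (-185 to -168). It set the 3 Fleur11 libraries at 21 dpi, the 3 12CS_044 libraries at 12 dpi and Fleur11 at 12 dpi replicate 1 apart from the remaining libraries. On 922 genes, every library of Fleur11 at 21 dpi and of 12CS_044 at 12 dpi lay over 2-fold beyond every library of the other 6 groups on the same side, with Fleur11 at 12 dpi left out. Of these genes, 601 were lower and 321 higher in this pair of groups. The rule used CPM without TMM factors, which were 0.717 to 0.890 in this pair and 0.971 to 1.16 in the other 6 groups. Genes could thus pass as lower more easily than as higher, so no direction is read from these numbers. The pair of groups with the next highest number, Fleur11 and 12CS_051 at 21 dpi, had 249 such genes, all of them higher. Replicate 1 of Fleur11 at 12 dpi also held 879 genes above 1 CPM that stayed below 0.1 CPM in all other libraries, against at most 3 such genes in any other library. Its lowest correlation with a replicate of its group was 0.738 across genes, and the lowest correlation among all other replicate pairs was 0.943 (genes are not independent replicates).

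**Figure D1:**
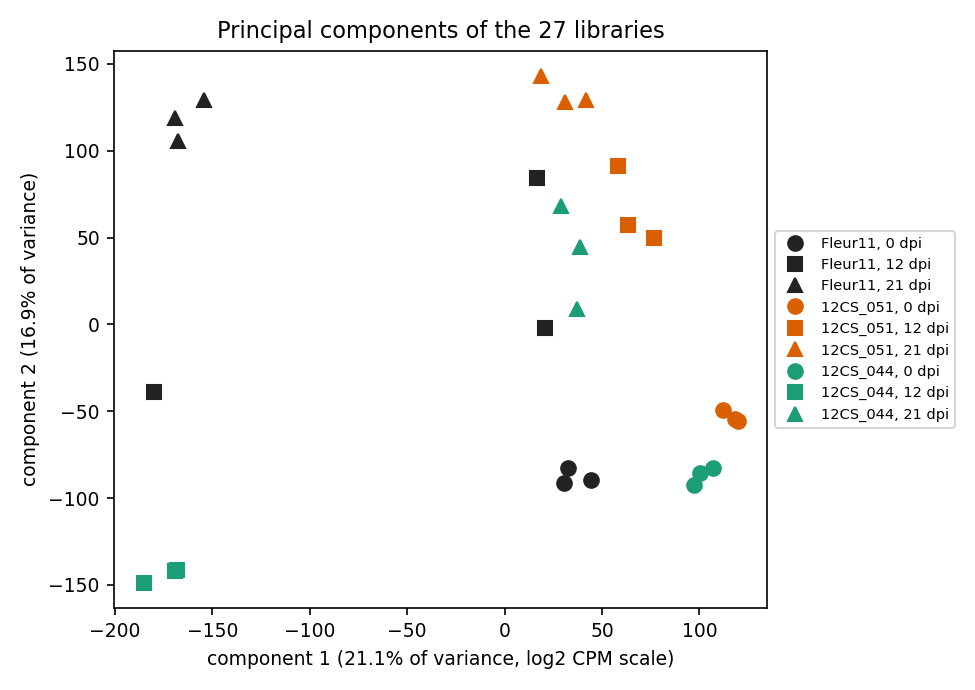
Each point is 1 library, placed by principal components 1 (21.1% of the variance) and 2 (16.9%) of its log2 CPM values, with colour for genotype and shape for day. Fleur11 at 21 dpi, 12CS_044 at 12 dpi and 1 Fleur11 library at 12 dpi lie on the left, and the other libraries on the right.

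The change in Fleur11 after inoculation was compared first. Between 0 and 12 dpi, 9412 genes rose and 6327 fell in Fleur11 (15739 in all). Gene arahy.Tifrunner.gnm1.ann1.8L903M had no counts at 0 dpi and 68.6 ± 116 CPM (SD, n = 3) at 12 dpi (edgeR adjusted p = 0.0019), with 3.06, 203 and 0.137 CPM in its libraries. It was at least 2191-fold higher with all libraries and at least 38.7-fold higher without replicate 2 at 12 dpi. Gene arahy.Tifrunner.gnm1.ann1.548AAM fell from 73.5 ± 42.7 CPM to no counts, at least 3240.5-fold lower (adjusted p = 0.000242). With the 6 compared libraries alone, 309 genes were called (112 higher, 197 lower), and without Fleur11 at 12 dpi replicate 1 the count was 15480 (7914 higher, 7566 lower).

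Between 12 and 21 dpi, 8048 genes rose and 10436 fell in Fleur11 (18484 in all). Gene arahy.Tifrunner.gnm1.ann1.548AAM rose from no counts to 218 ± 18.4 CPM, at least 9957-fold higher (adjusted p = 4.09e-05). Gene arahy.Tifrunner.gnm1.ann1.TN4W22 rose from no counts to 57.8 ± 3.96 CPM, at least 2646-fold higher (adjusted p = 0.0121). Among falling genes, arahy.Tifrunner.gnm1.ann1.V70XEM had 74.2 ± 128 CPM at 12 dpi, nearly all from replicate 1 (222 CPM), and no counts at 21 dpi. With the 6 compared libraries alone, 2347 genes were called, and the larger side turned (1256 higher, 1091 lower).

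Between 0 and 21 dpi, a comparison added after the data were seen, 8248 genes rose and 7982 fell in Fleur11. Gene arahy.Tifrunner.gnm1.ann1.SU9WSI rose from no counts to 3135 ± 912 CPM, at least 115058-fold higher (adjusted p = 0.00119). Gene arahy.Tifrunner.gnm1.ann1.9R3RK8 rose from no counts to 3208 ± 954 CPM (adjusted p = 0.00354). Gene arahy.Tifrunner.gnm1.ann1.NJU12A fell from 61.2 ± 14.9 CPM to no counts, at least 1772-fold lower (adjusted p = 1.26e-05). Gene arahy.Tifrunner.gnm1.ann1.G822GZ fell from 66.9 ± 42.3 CPM to no counts, at least 1950.1-fold lower (adjusted p = 1.09e-05), or at least 1226-fold without replicate 1 at 0 dpi. Time, plant age, inoculation and the presence of nodules cannot be separated in the comparisons with 0 dpi.

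A set of 155 genes, defined after the data were seen, was nearly silent at 0 dpi and above 20 CPM in every Fleur11 library at 21 dpi. At 0 dpi its summed level was 6.498 ± 1.06 CPM in Fleur11, 7.78 ± 0.357 CPM in 12CS_051 and 8.11 ± 1.25 CPM in 12CS_044. At 21 dpi the set took 4.75 ± 0.143% of all counts in Fleur11 and 1.05 ± 0.186% in 12CS_051. In 12CS_044 at 21 dpi it took 0.0676 ± 0.0896%, with 16.2, 316 and 1696 summed CPM in its libraries. All 155 genes were called higher at 21 than at 0 dpi in Fleur11 and in 12CS_051, and 86 of them in 12CS_044 (12 without replicate 4 at 21 dpi, 134 without Fleur11 at 12 dpi replicate 1). All 155 being higher in Fleur11 is partly fixed by how the set was chosen.

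Against Fleur11 at 21 dpi, the summed level of the set was 4.54 times lower in 12CS_051 and 70.2 times lower in 12CS_044. Both differences had an exact permutation p of 0.1 (two-sided), the smallest that 3 against 3 libraries allow, and the libraries did not overlap. All 155 genes were called lower in 12CS_044. By the interaction from 0 to 21 dpi, 19 of the 155 genes rose less in 12CS_044 than in Fleur11 and 0 in 12CS_051. These numbers were 29 and 38 with the compared libraries alone, and 56 and 6 of 117 with DESeq2. In 12CS_044 it was 10 without Fleur11 at 0 dpi replicate 1 and 33 without 21 dpi replicate 4. The median log2 fold change of the interaction was -6.34 in 12CS_044 and -2.52 in 12CS_051. The set was chosen near 0 at 0 dpi, where counts are few, so genes not called cannot be taken to have risen alike. In 12CS_051, 8 of the 155 genes were called lower, with a median log2 fold change of -2.44 over the set. When the set was defined in 12CS_051 instead (74 genes), its summed level was 4.45 times higher in Fleur11 than in 12CS_051. Of these genes, edgeR called 0 lower in 12CS_051 and DESeq2 0 of the 59 to which it gave an adjusted p. An unadjusted p lay below 0.05 for 5 (edgeR) and 2 (DESeq2), and all 74 lay below Fleur11 with edgeR. Both methods took the spread from all 27 libraries, so their counts are not independent. The share called lower in 12CS_051 was 5.16% with all 27 libraries, 99.4% with the 6 compared libraries alone, and 17.4% without Fleur11 at 12 dpi replicate 1. It was 2.58% and 3.23% without replicates 1 and 2 of 12CS_051 at 21 dpi, and without replicate 4 of 12CS_044 at 21 dpi the level in Fleur11 was 285 times that in 12CS_044.

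At 12 dpi the set was uneven within Fleur11, with 139, 6345 and 12.9 summed CPM in its 3 libraries. The 3 libraries of 12CS_051 had 1065 to 2518 summed CPM at 12 dpi. The exact permutation p of the difference from Fleur11 was 0.4 for either line. Of the 155 genes, 2 were called lower in 12CS_051 than in Fleur11 and 0 higher, and 141 were called lower in 12CS_044 and 2 higher. Both counts depended on Fleur11 replicate 2. Without it 16 genes were called lower in 12CS_044, and 105 higher in 12CS_051. With the compared libraries alone 0 genes were called lower in either line. That fit tested only 25 of the 155 genes for 12CS_044 and 149 for 12CS_051. With the replicate block 95 were called lower in 12CS_044. By the interaction from 0 to 12 dpi, 18 of the 155 genes were called lower and 2 higher in 12CS_044, and 0 in 12CS_051. For 12CS_051 there were 9 higher without Fleur11 at 12 dpi replicate 2, and 5 higher and 6 lower with DESeq2. Here too the set was chosen near 0 at 0 dpi, so genes not called cannot be taken to have changed alike. The number lower in 12CS_044 was 5 without Fleur11 at 12 dpi replicate 2 and 6 with the replicate block. It was 2 of 33 tested with the compared libraries alone, and 64 of 117 with DESeq2. In 12CS_044 at 12 dpi the set had 1003 ± 23.4 summed CPM, of which 2 genes held 51.3% and 47.0%, and at most 6 of its genes exceeded 1 CPM in any library, against at least 110 genes in each library of 12CS_051. The subset of 60 genes above 100 CPM in Fleur11 at 21 dpi summed to 10.3 ± 3.22 CPM in 12CS_044 and to 1311 ± 617 CPM in 12CS_051 at 12 dpi. Between the lines at 12 dpi, 116 genes of the set were called higher and 2 lower in 12CS_051 (71 and 2 without 12CS_044 replicate 3). At 21 dpi 3 were called higher and 0 lower, and the number higher was 39 without Fleur11 at 12 dpi replicate 1, 21 with DESeq2 and 0 without 12CS_044 replicate 2 or 3.

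**Figure D2:**
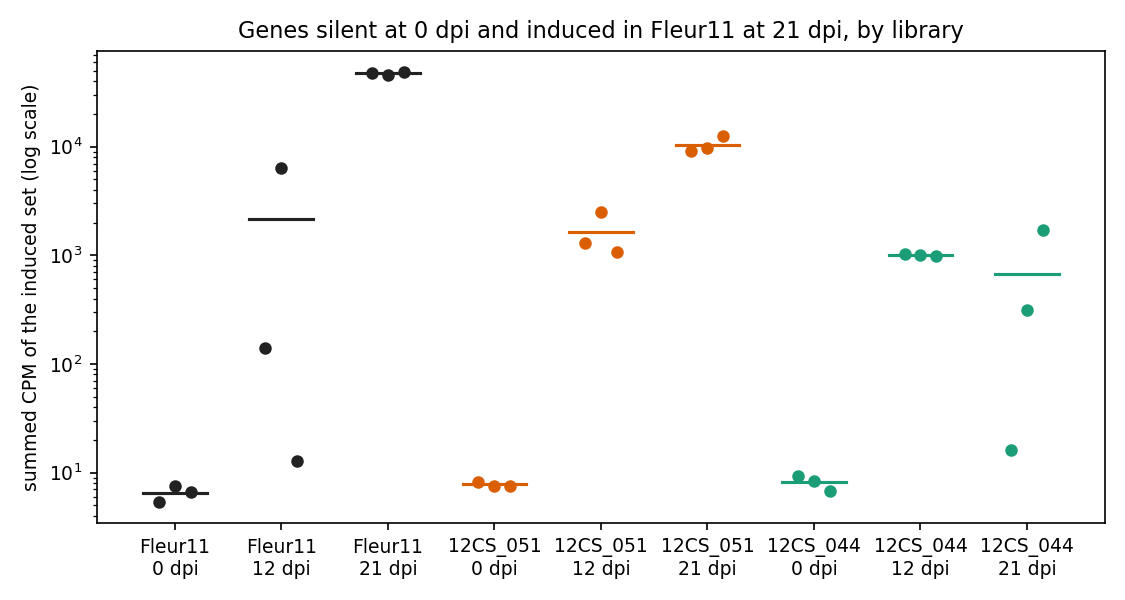
Summed CPM (log axis) of the 155 genes nearly silent at 0 dpi and above 20 CPM in every Fleur11 library at 21 dpi; points are libraries and bars are group means. Fleur11 libraries at 21 dpi had 45826 to 48469 summed CPM, those of 12CS_051 9040.3 to 12562, and those of 12CS_044 16.2 to 1696.

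Changes over time within 12CS_051 were tested in the same way. Between 0 and 12 dpi, 3625 genes rose and 2575 fell, and between 12 and 21 dpi 443 rose and 434 fell. Between 0 and 21 dpi, 5631 rose and 4436 fell. Gene arahy.Tifrunner.gnm1.ann1.8L903M, named for Fleur11, went from no counts to 76.5 ± 42.6 CPM at 12 dpi and 210 ± 21.7 CPM at 21 dpi in 12CS_051, beside 260 ± 65.5 CPM in Fleur11 at 21 dpi. Gene arahy.Tifrunner.gnm1.ann1.9R3RK8 had 265 ± 170 CPM in 12CS_051 at 21 dpi. Without Fleur11 at 12 dpi replicate 1, the counts were 14295 (12 against 0 dpi), 5247 (21 against 12 dpi) and 18210 (21 against 0 dpi), and the common biological coefficient of variation was 35.5% instead of 42.9%. With the compared libraries alone, 10929 genes were called for 12 against 0 dpi, against 309 in Fleur11, and without that library 14295 against 15480.0. For 21 against 12 dpi, leaving out a library of 12CS_051 gave 347 and 423 genes (replicates 1 and 3 at 12 dpi) and 359, 392 and 177 genes (replicates 1, 2 and 3 at 21 dpi), and for 12 against 0 dpi it gave 3605, 3430.0 and 3420.0 genes (replicates 1 and 4 at 0 dpi, replicate 2 at 12 dpi).

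Within 12CS_044, 11927 genes rose and 11608 fell between 0 and 12 dpi, and 11328 rose and 11286 fell between 12 and 21 dpi. Between 0 and 21 dpi, 6830 rose and 5428 fell. Gene arahy.Tifrunner.gnm1.ann1.8L903M had 0.0103 ± 0.0179, 0.327 ± 0.0746 and 5.83 ± 6.96 CPM at 0, 12 and 21 dpi in 12CS_044. Gene arahy.Tifrunner.gnm1.ann1.9R3RK8 had 27.8 ± 43.8 CPM at 21 dpi, an SD above its mean. The group at 12 dpi thus differed from the days before and after it by more genes than those days differed from each other, and it shared the 922 genes above with Fleur11 at 21 dpi. Without Fleur11 at 12 dpi replicate 1, the count for 21 against 0 dpi was 20336.

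The lines were then compared with Fleur11 at each day. At 0 dpi, 1014 genes were higher and 2917 lower in 12CS_051. Gene arahy.Tifrunner.gnm1.ann1.0Z44XW had 26.9 ± 5.80 CPM in the line and no counts in Fleur11, at least 985-fold higher (edgeR adjusted p = 4.09e-05). Gene arahy.Tifrunner.gnm1.ann1.36QZ6D had no counts in the line and 99.3 ± 7.40 CPM in Fleur11, at least 3664-fold lower (adjusted p = 2.68e-06). In 12CS_044 at 0 dpi, 926 genes were higher and 3067 lower. Gene arahy.Tifrunner.gnm1.ann1.SHB49X had 45.4 ± 7.45 CPM in 12CS_044 and no counts in Fleur11, at least 1645-fold higher (adjusted p = 0.00074). Gene arahy.Tifrunner.gnm1.ann1.N0BVKE had no counts in 12CS_044 and 76.9 ± 13.8 CPM in Fleur11, at least 2756-fold lower (adjusted p = 7.05e-05).

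Both counts at 0 dpi moved with the libraries in the fit, and so did the split into higher and lower genes. Without Fleur11 at 12 dpi replicate 1, 9037 (12CS_051; 3351 higher, 5686 lower) and 9081 (12CS_044; 3242 and 5839) genes were called. With the compared libraries alone they were 9901 (4015 and 5886) and 9715 (3757 and 5958), and DESeq2 called 1852 higher and 3639 lower in 12CS_051 and 1813 and 3676 in 12CS_044. With a minimum absolute log2 fold change of 1 the part that was lower was larger than with all called genes (429 higher and 1907 lower in 12CS_051, 334 and 1956 in 12CS_044), as it was without a filter on low counts (784 and 2591, 675 and 2775) and with the replicate block (832 and 2532, 745 and 2675). Without Fleur11 at 0 dpi replicate 2, or 12CS_051 at 0 dpi replicate 2 or 4, 2603, 2554 and 2597 genes were called for 12CS_051, and without 12CS_044 at 0 dpi replicate 3, 2521 for 12CS_044.

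At 12 dpi, 535 genes were higher and 3750 lower in 12CS_051 than in Fleur11. Gene arahy.Tifrunner.gnm1.ann1.S1KKCT had 86.8 ± 4.64 CPM in 12CS_051 and 4 counts in Fleur11, a ratio of 2941 (exact 95% interval 1148 to 10798; adjusted p = 7.63e-10). Gene arahy.Tifrunner.gnm1.ann1.LZ5KER had no counts in 12CS_051 and 43.7 ± 11.9 CPM in Fleur11, at least 1252-fold lower (adjusted p = 3.31e-11). With the 6 compared libraries alone, 116 genes were called (17 higher, 99 lower), and with the replicate number as a block 2029. Leaving out 1 library gave 1023 (302 higher, 721 lower), 11875 (3615 and 8260.0) and 8126 genes (1451 and 6675) for Fleur11 replicates 1, 2 and 3, and 752, 888 and 2466 genes (12CS_051 replicates 1, 2 and 3).

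In 12CS_044 at 12 dpi, 9416 genes were higher and 11951 lower than in Fleur11. Gene arahy.Tifrunner.gnm1.ann1.U4C9QK had 33.8 ± 0.564 CPM in 12CS_044 and no counts in Fleur11, at least 1539-fold higher (adjusted p = 7.77e-05). It had 39.2 ± 4.87 CPM in Fleur11 at 21 dpi, but 1.30 ± 1.19 and 3.48 ± 2.93 CPM in 12CS_044 at 0 and 21 dpi. Gene arahy.Tifrunner.gnm1.ann1.87RFWK had no counts in 12CS_044 and 80.7 ± 10.02 CPM in Fleur11, at least 2708-fold lower (adjusted p = 3.66e-13). With the 6 compared libraries alone, 5898 genes were called. The 12CS_044 libraries at 12 dpi are those that shared 922 genes with Fleur11 at 21 dpi, so these counts rest on a group that stood apart from the rest.

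At 21 dpi, 7093 genes were higher and 7276 lower in 12CS_051 than in Fleur11, and 8058 were higher and 8256 lower in 12CS_044. Gene arahy.Tifrunner.gnm1.ann1.NJU12A, which fell in Fleur11, had 33.1 ± 1.504 CPM in 12CS_051 and 57.9 ± 7.31 CPM in 12CS_044 and no counts in Fleur11 (at least 970.1-fold and at least 1701-fold higher; adjusted p = 3.3e-05 and 1.41e-05). Gene arahy.Tifrunner.gnm1.ann1.A7KEBQ had 47.0 ± 10.6 CPM in 12CS_051 and 58.0 ± 1.09 CPM in 12CS_044 and no counts in Fleur11 (adjusted p = 0.00477 and 0.00356). Gene arahy.Tifrunner.gnm1.ann1.FB1AMA had no counts in 12CS_051 and 36.5 ± 1.16 CPM in Fleur11, at least 1120.1-fold lower (adjusted p = 7.36e-13). Gene arahy.Tifrunner.gnm1.ann1.Q5JGPT had no counts in 12CS_044 and 37.0 ± 4.98 CPM in Fleur11, at least 1036-fold lower (adjusted p = 0.00531). At 12 dpi, however, it had 35.4 ± 2.71 CPM in 12CS_044 and 2.25 ± 0.851 CPM in Fleur11. The Fleur11 libraries at 21 dpi are those that shared 922 genes with 12CS_044 at 12 dpi, so both counts rest on a group that stood apart from the rest.

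**Figure D3:**
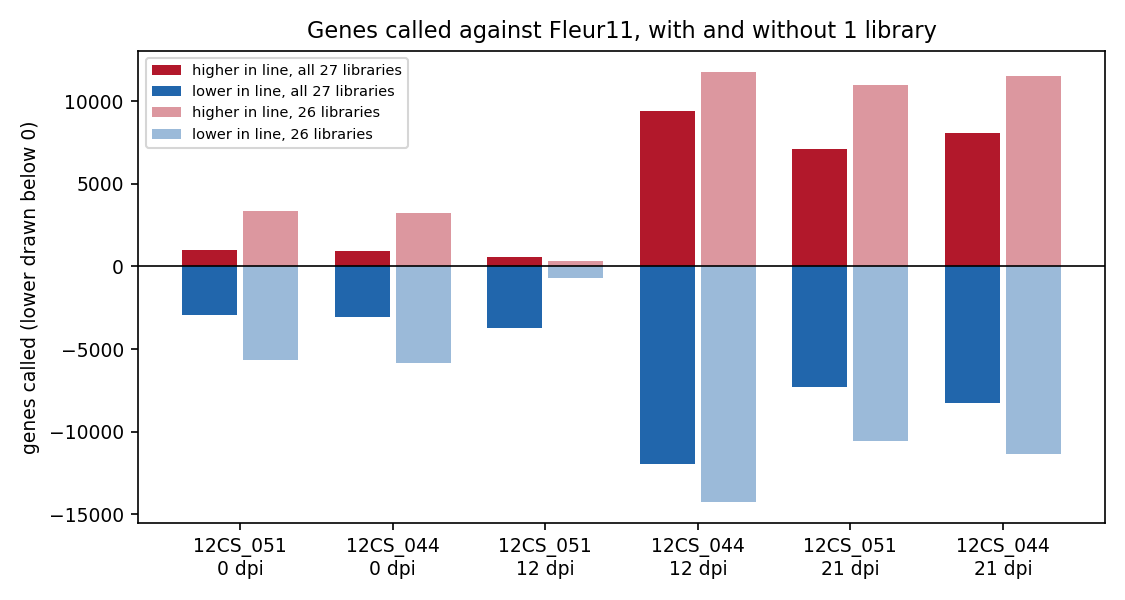
Bars give the number of genes called higher (above 0) or lower (below 0) in each line than in Fleur11 at 0, 12 and 21 dpi, with all 27 libraries (dark) and without Fleur11 at 12 dpi replicate 1 (light). The count for 12CS_051 at 12 dpi was 4285 with all libraries and 1023 without that library, while the other counts rose.

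Both lines were called in the same direction against Fleur11 for 2725 genes at 0 dpi (534 higher, 2191 lower), 1536 at 12 dpi (170 higher, 1366 lower) and 12280 at 21 dpi (6141 higher, 6139 lower). Independent lists of these sizes would share 21.4 higher and 204 lower genes at 0 dpi, 115 and 1022 at 12 dpi, and 1303 and 1370.0 at 21 dpi. Simulated groups without any difference, set against shared Fleur11 libraries, gave a median of 26.5 shared genes at 12 dpi. Their lists had medians of 182.5 and 187 genes, all false calls. All simulated libraries were drawn alike from the group mean, so none stood apart as Fleur11 at 12 dpi replicate 1 did. What that library adds to the overlap at 12 dpi was thus not simulated. At 0 and 21 dpi the simulated lists had a median of 0 genes, so they say nothing about the overlap that shared libraries add to longer lists. Opposite directions were called for 5, 861 and 45 genes at 0, 12 and 21 dpi. The 3 Fleur11 libraries of a day are too few to be split, so part of the excess may come from the shared controls. Without Fleur11 at 12 dpi replicate 1 the shared counts were 6589, 351 and 18465, without Fleur11 at 0 dpi replicate 2 or 3 they were 1748 and 1755 at 0 dpi, and with the compared libraries alone they were 6921, 17 and 16082. At 12 dpi they were 4674 and 3472 without Fleur11 replicate 2 or 3, 208, 276 and 829 without 12CS_051 replicate 1, 2 or 3, and 601 with the replicate number as a block.

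The lines were compared directly with each other. At 0 dpi, 179 genes were higher and 352 lower in 12CS_051 than in 12CS_044. Gene arahy.Tifrunner.gnm1.ann1.GIKJ41 had 22.0 ± 1.79 CPM in 12CS_051 and no counts in 12CS_044, at least 794-fold higher (adjusted p = 8.79e-09). Gene arahy.Tifrunner.gnm1.ann1.K53WYZ had no counts in 12CS_051 and 78.6 ± 7.46 CPM in 12CS_044, at least 2921-fold lower (adjusted p = 1.35e-07). At 12 dpi, 11478 genes were higher and 11110 lower, a comparison that rests on the 12CS_044 group that stood apart. Gene arahy.Tifrunner.gnm1.ann1.53RC8Z had no counts in 12CS_051 and 267 ± 65.7 CPM in 12CS_044 at 12 dpi, at least 7219-fold lower (adjusted p = 4.92e-05). At 21 dpi, 423 genes were higher and 413 lower. Gene arahy.Tifrunner.gnm1.ann1.XB6NYF had 30.6 ± 13.9 CPM in 12CS_051 and no counts in 12CS_044 at 21 dpi, at least 838-fold higher (adjusted p = 0.00256). At 21 dpi 2087 genes were called without Fleur11 at 12 dpi replicate 1, 545 without 12CS_051 replicate 3, 509 and 540.0 without 12CS_044 replicates 2 and 3, 1491 with the compared libraries alone and 1570.0 with DESeq2. At 0 dpi DESeq2 called 945 genes.

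Interactions tested whether a line changed over time differently from Fleur11. For 12CS_051, 353 genes differed in their change from 0 to 12 dpi (246 more positive, 107 more negative), 8572 in their change from 12 to 21 dpi (4859 and 3713) and 6777 from 0 to 21 dpi (3711 and 3066). Gene arahy.Tifrunner.gnm1.ann1.U4C9QK went from 10.8 ± 1.51 CPM to no counts between 0 and 12 dpi in Fleur11 and from no counts to 2.02 ± 0.773 CPM in 12CS_051 (adjusted p = 0.00295). For 12CS_044, 15828 genes differed in their change from 0 to 12 dpi (7672 and 8156), 21802 from 12 to 21 dpi (11774 and 10028) and 8717 from 0 to 21 dpi (4807 and 3910). Gene arahy.Tifrunner.gnm1.ann1.LL8CI2 went from no counts to 32.9 ± 21.2 CPM between 0 and 12 dpi in Fleur11 and from 50.7 ± 1.89 to 3.70 ± 6.41 CPM in 12CS_044 (adjusted p = 0.0133). Gene arahy.Tifrunner.gnm1.ann1.CE0UAC went from 14.0 ± 12.1 CPM to no counts between 12 and 21 dpi in Fleur11 and from no counts to 13.3 ± 8.48 CPM in 12CS_044 (adjusted p = 7.91e-06).

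Of the interactions, the smallest was the least stable. For 12CS_051 from 0 to 12 dpi, 12 genes were called with the compared libraries alone, 235 with the replicate number as a block and 1803 with DESeq2, whose split was 838 more positive and 965 more negative. Leaving out 1 library gave 198 and 185 genes (Fleur11 at 0 dpi replicates 2 and 3), 1349, 2484 and 1999 (Fleur11 at 12 dpi replicates 1, 2 and 3) and 194 and 203 (12CS_051 at 0 dpi replicates 2 and 4). With the compared libraries alone, the change from 12 to 21 dpi differed for 2413 genes in 12CS_051 and the change from 0 to 12 dpi for 9672 in 12CS_044. For the latter the larger side turned with the compared libraries alone (5249 more positive, 4423 more negative) and with the replicate block (7452 and 7221). From 0 to 21 dpi, 14196 (12CS_051) and 16440.0 (12CS_044) genes were called without Fleur11 at 12 dpi replicate 1. The larger side turned for that change with RLE size factors (3374 more positive and 3452 more negative in 12CS_051, 4322 and 4378 in 12CS_044) and with DESeq2 (4435 and 4584 in 12CS_051, 5449 and 5598 in 12CS_044).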

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

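Chosen after the results were seen were the tests of genotype labels, of exchanged days, of RNA mixed in and of a shared library batch, and the splits for both lines against Fleur11 at each day, for Fleur11 at 12 against 0 and 21 against 12 dpi and for 12CS_051 at 12 against 0 dpi.

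The first pattern is that 12CS_044 at 12 dpi stood apart: 23535 genes differed from 0 dpi in the same line, and 922 genes set the group apart from the others together with Fleur11 at 21 dpi. Against a wrong genotype label, 3 of its 3 libraries held a larger share of 12CS_044 markers than of either other genotype's. These shares were at least 94.2% against at most 16.1% with the marker sets pooled, and at least 83.3% against at most 30% in single sets. After all libraries were thinned to the lowest total, 22814 genes were called. The totals before thinning overlapped between 12 dpi (29.8 to 34.1 M) and 0 dpi (32.3 to 39.6 M) in this line. That argues against library size, and it makes thinning a weak test of it. An exchange of the labels of 12 and 21 dpi cannot be told apart from a true difference: in the induced set 65 genes rose and 2 fell from 12 to 21 dpi, the way of the labels (4 and 2 without 21 dpi replicate 4), but its mean summed level was higher at 12 dpi (1003 against 676 CPM), carried by 2 genes, and its subset of 60 genes overlapped between the days (10.3 ± 3.22 CPM at 12 dpi, and 8.34, 247 and 1458 CPM at 21 dpi). Across 36856 genes above 1 CPM on average and outside the induced set (taken with a minimum of 5 CPM), which are not independent replicates, the correlation with the change in Fleur11 from 0 to 21 dpi was higher at 12 than at 21 dpi (0.360 against 0.282, a difference of 0.0784, below the 0.1 set for an exchange), while in 12CS_051 it was 0.244 at 12 and 0.384 at 21 dpi. A library batch that held all of Fleur11 at 21 dpi and all of 12CS_044 at 12 dpi cannot be told apart from these groups, because the labels give no batch, and a response of 12CS_044 at 12 dpi stays open as untested; such a batch, but not such a response, may underlie the 12280 genes shared by both lines at 21 dpi, since these are measured against the Fleur11 libraries concerned.

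The second pattern is that Fleur11 at 12 dpi replicate 1 stood apart from replicates 2 and 3, with 879 genes above 1 CPM that stayed below 0.1 CPM elsewhere. A wrong genotype label is argued against by its Fleur11 markers, of which 92.7% were detected, against 30.6% of the markers of another genotype (at least 80% and at most 41.7% in single marker sets). RNA of another source that lowered all other genes alike is argued against as the whole cause by the spread of log2 ratios to replicates 2 and 3 over 453 abundant genes, an SD of 1.39 against 0.274 between those replicates, but as a part of the cause it stays open, since the median log2 ratio was -0.625 and 2554 genes had counts in this library alone. A library batch shared with Fleur11 at 21 dpi and 12CS_044 at 12 dpi stays open: on the 922 genes, replicate 1 lay nearer to these groups for 55.4% of the genes, replicate 2 for 0.759% and replicate 3 for 3.58%, and 55.4% lies between what a full share in the batch and no share would give. No biological explanation was tested, since the labels set this library apart from its replicates in no way.

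The third pattern is 159 genes with at most 3 counts in total over a group and at least 20 CPM in every library of another (Fleur11 at 12 dpi left out), which include 36 of the 66 IDs ranked highest by fold change. Reads shared between near-identical copies may give such values: 43.4% of the genes had a partner gene that offset them, against 82.4% of control genes of like level and spread. That met the bound set beforehand for no such sharing, but the search was judged void after its result was seen, because a partner was found for 82.4% of genes that do not show the pattern, so sharing between copies cannot be told apart from regulation here. A variant of a line against the reference met the bound set beforehand against it, since 14 of the 159 genes (8.81%) followed the genotype at every day. That share may be too low, because over 3 counts in a group at any day ended the match. Gene arahy.Tifrunner.gnm1.ann1.LZ5KER failed so, with 0, 0 and 0.0912 CPM in 12CS_051 and 28.5 to 56.3 CPM in 12CS_044. Gene arahy.Tifrunner.gnm1.ann1.87RFWK did not follow the genotype, with 28.5, 0 and 79.6 CPM in 12CS_044 at 0, 12 and 21 dpi. A variant thus stays open for an unknown part of these genes. Regulation of these genes by day and genotype stays open and was not tested separately.

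Genes were called for every interaction of a line with time, and 40 splits of the same libraries, the real one included, were tried for each. The number of splits was lowered to 40, for running time, after a run with more splits had been seen. Which shares lay under 0.05 came out alike in both runs. Each day was split on its own, so a split can by its draw keep the real groups of 1 day whole. Such a split holds the real difference between genotypes at that day, and which splits did so was not looked at. High counts in other splits are therefore read neither as a structure in the samples nor as a clean measure of chance. For 12CS_051 from 0 to 12 dpi (353 genes), 4 of the 40 splits called as many, with 2651 as the highest other, and chance cannot be excluded. For 12CS_051 from 12 to 21 dpi (8572 genes), 5 of the 40 splits called as many, with 11007 as the highest other, and chance cannot be excluded. For 12CS_051 from 0 to 21 dpi (6777 genes), 2 of the 40 splits called as many, with 8214 as the highest other, and chance cannot be excluded. For 12CS_044 from 0 to 21 dpi (8717 genes), 2 of the 40 splits called as many, with 9503 as the highest other, and chance cannot be excluded. For 12CS_044 from 0 to 12 dpi (15828 genes), 1 of the 40 splits, the real one, called as many, with 13293 genes in the highest other. From 12 to 21 dpi (21802 genes) it was also 1, with 13905 genes in the highest other. Both shares lay under 0.05, without a correction for the number of interactions. The splits mix genotypes within a day, which removes the difference between genotypes along with the interaction. They thus cannot exclude chance for the interaction alone, nor a batch.

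For comparisons of 3 with 3 libraries there are 10 splits, too few for a share under 0.05, and in each of the 18 comparisons 1 split, the real one, called as many genes. The highest other split against the real count was 0 against 3931 for 12CS_051 and 1 against 3993 for 12CS_044 compared with Fleur11 at 0 dpi, 2683 against 4285 and 9891 against 21367 at 12 dpi, and 1 against 14369 and 1 against 16314 at 21 dpi. In Fleur11 it was 2277 against 15739 (12 with 0 dpi), 7029 against 18484 (21 with 12 dpi) and 0 against 16230 (21 with 0 dpi). In 12CS_051 it was 1 against 6200, 2 against 877 and 0 against 10067 for the same days, and in 12CS_044 1 against 23535, 1 against 22614 and 1 against 12258. Between the lines it was 2 against 531, 0 against 22588 and 0 against 836 at 0, 12 and 21 dpi.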

How the results depend on the processing

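Leaving out Fleur11 at 12 dpi replicate 1 from comparisons that do not include it, the replicate number of the table's columns as a block, every alternative for 21 against 0 dpi and for the induced set, and the alternatives for the shared counts other than DESeq2 and the fold-change minimum were chosen after the data were seen. RLE size factors kept all 29 counts and shares within 1.5 times, DESeq2 25 of 29, no filter on low counts 28 of 29, and 0 named genes reversed where they were tested. Under DESeq2, 87 named entries stayed called and 9 of 96 had no adjusted p, and under the replicate block 16 of 96 were no longer called. Without a filter 5 of 96 were no longer called, and with the compared libraries alone 15 were not called and 3 not tested, both looked at for named genes after the data were seen. Leaving out 1 library ended the call of 25 of the 96 entries at least once (137 of 720 fits of an entry), and 71 stayed called throughout. DESeq2 moved the median log2 fold change of all genes by over 0.1 in the comparisons with Fleur11 at 12 dpi, for example by 0.16 in Fleur11 at 12 against 0 dpi and by -0.14 in 12CS_044 against Fleur11 at 12 dpi. Tests of gene lists, the scan along chromosomes and the block by label number were not run, since names, positions and 10 label numbers could not be tied to the table. Depth limits low genes: a gene with no counts at 12 dpi in Fleur11 is only bounded by 3 counts over the group.

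With a minimum absolute log2 fold change of 1, fewer genes pass by construction: 2336 and 2290.0 at 0 dpi (12CS_051 and 12CS_044 against Fleur11), 12344 for 12CS_044 at 12 dpi, 7479 and 8801 at 21 dpi, 7435, 9900.0 and 9171 in Fleur11 (12 with 0, 21 with 12, 21 with 0 dpi), 2655, 362 and 4924 in 12CS_051, 14166, 13480.0 and 5750.0 in 12CS_044, 13583 between the lines at 12 dpi, 5266 and 3966 for the interactions of 12CS_051 (21 with 12, 21 with 0 dpi), 5386 for that of 12CS_044 (21 with 0 dpi), and 1506 and 6190.0 shared by both lines at 0 and 21 dpi.

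With the compared libraries alone, which changes the spread and the residual degrees of freedom, the counts were 9901 and 9715 at 0 dpi and 116 and 5898 at 12 dpi (lines against Fleur11), 309 and 2347 in Fleur11 (12 with 0, 21 with 12 dpi), 10929, 1527 and 18212 in 12CS_051 (12 with 0, 21 with 12, 21 with 0 dpi), 19558 in 12CS_044 (21 with 0 dpi), 1491 between the lines at 21 dpi, 12, 2413 and 14500.0 for the interactions of 12CS_051, 9672 and 16397 for those of 12CS_044 (12 with 0, 21 with 0 dpi), 6921 and 17 shared at 0 and 12 dpi, and 99.4% of the induced set lower in 12CS_051.

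DESeq2 called 2344 genes in 12CS_051 (21 with 12 dpi), 1803 for its interaction from 0 to 12 dpi, and 945 and 1570.0 between the lines at 0 and 21 dpi; without a filter on low counts 522 genes were called in 12CS_051 (21 with 12 dpi). The cause of these changes was not tested. The side with more called genes, higher or lower, turned under 5 of the 6 settings other than leaving out a library for 12CS_044 at 12 with 0 dpi and under 3 of 6 for 12CS_044 at 21 with 12 dpi and for the lines at 21 dpi, so no direction is read from these counts. It also turned under at least 1 setting for Fleur11 over time, for 12CS_051 at 21 with 12 and 21 with 0 dpi, for 12CS_044 at 21 with 0 dpi and for the interactions of 12 with 0 and 21 with 0 dpi, and for the lines against Fleur11 at 21 dpi when a library was left out. With the replicate block, 2029 genes were called for 12CS_051 at 12 dpi, 235 for its interaction from 0 to 12 dpi and 601 shared at 12 dpi. Replicate numbers do not pair libraries: over 18 comparisons the correlations of residuals between libraries of the same number ran from -0.0743 to 0.0560. For the induced set, the share called lower in 12CS_051 was 22.0% with a minimum of 5 CPM, 1.67% with 100 CPM and 0% with the set defined in 12CS_051, where 5 genes (edgeR) and 2 genes (DESeq2, 0 adjusted) had an unadjusted p below 0.05.

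Leaving out 1 library at a time, the counts against Fleur11 ranged from 2554 (without 12CS_051 replicate 2) to 9037 and from 2521 (without 12CS_044 replicate 3) to 9081 at 0 dpi, and from 752 (without 12CS_051 replicate 1) to 11875 (without Fleur11 replicate 2) for 12CS_051 at 12 dpi. In 12CS_051 they ranged from 3420.0 (without 12 dpi replicate 2) to 14295, from 177 to 5247 and from 6803 to 18210.0 (177 and 6803 without 21 dpi replicate 3), and in 12CS_044 at 21 with 0 dpi from 8688 to 20336. Between the lines at 21 dpi they ranged from 509 (without 12CS_044 replicate 2) to 2087. Interactions of 12CS_051 ranged from 185 (without Fleur11 0 dpi replicate 3) to 2484 (without Fleur11 12 dpi replicate 2) for 12 with 0 dpi and from 4992 to 14196 for 21 with 0 dpi, and that of 12CS_044 from 6738 to 16440.0. Shared counts ranged from 1748 (without Fleur11 replicate 2) to 6589, from 208 (without 12CS_051 replicate 1) to 4674 (without Fleur11 replicate 2) and from 10142 to 18465 at 0, 12 and 21 dpi. At 12 dpi, 141 genes of the induced set were lower in 12CS_044, against 0 with the compared libraries alone (25 of the genes tested), 95 with the replicate block, 109 of 117 with DESeq2, 16 without Fleur11 replicate 2 and 99 without 12CS_044 replicate 3. Within 12CS_044, 86 genes of the set were higher at 21 than at 0 dpi, against 12 without 21 dpi replicate 4, 18 without 0 dpi replicate 3, 44 with the replicate block and 14 of 21 tested with the compared libraries alone, and 65 were higher at 21 than at 12 dpi, against 4 without 21 dpi replicate 4 and 11 with the replicate block. The share of the induced set lower in 12CS_051 ranged from 2.58% (without 21 dpi replicate 1) to 17.4%, and the ratio of Fleur11 to 12CS_044 from 47.2 to 285 (without 21 dpi replicate 4). Unless another library is named, the highest value is that without Fleur11 at 12 dpi replicate 1.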

Other observations

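The counts and shares in this part were chosen after the data were seen, although several rest on comparisons planned before. The genes that changed at least 2-fold in Fleur11 from 0 to 21 dpi were followed in the lines. Of the 4328 genes that rose in Fleur11, 45.1% were called higher in 12CS_051 at 21 dpi (1.46% lower) and 24.2% at 12 dpi (2.75% lower), and 34.3% in 12CS_044 at 21 dpi (3.72% lower) and 50.7% at 12 dpi (8.57% lower). Of all tested genes, 12.8%, 8.27%, 15.6% and 27.2% were called higher in these comparisons. Of the 4843 genes that fell in Fleur11, 35.99% were called lower in 12CS_051 at 21 dpi (3.39% higher) and 15.5% at 12 dpi (3.57% higher), and 37.6% in 12CS_044 at 21 dpi (4.89% higher) and 58.0% at 12 dpi (5.02% higher). Of all tested genes, 10.1%, 5.87%, 12.4% and 26.5% were called lower. Without Fleur11 at 12 dpi replicate 1, and for the same genes, the shares higher were 58.9%, 37.5%, 46.4% and 53.5% (22.4%, 16.9%, 25.3% and 30.2% of all genes), and the shares lower 52.9%, 35.1%, 52.6% and 68.7% (18.7%, 15.4%, 20.7% and 34.4% of all genes), in the same order. With all 27 libraries the highest shares were those of 12CS_044 at 12 dpi, where the shares of all genes were also the highest. The ranking is therefore not read as a likeness to Fleur11. Without Fleur11 at 12 dpi replicate 1 the highest share of rising genes was that of 12CS_051 at 21 dpi (58.9%), and of falling genes that of 12CS_044 at 12 dpi (68.7%). The group 12CS_044 at 12 dpi stood apart together with Fleur11 at 21 dpi on 922 genes. A batch shared by these groups, which stays open, thus bears on its shares. Whether these shares differ between the lines was not tested, and the changes of the genes in Fleur11 are favoured by their selection.

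Some genes separated the genotypes at every day. Above 1 CPM in every Fleur11 library and below 0.3 CPM in every 12CS_051 library were 99 genes, and 12 genes showed the opposite. Between Fleur11 and 12CS_044 these numbers were 18 and 2 genes, and without Fleur11 at 12 dpi replicate 1 they were 112 and 21 for 12CS_051 and 20 and 7 for 12CS_044. With limits of 2 and 0.1 CPM they were 35 and 4 for 12CS_051 and 7 and 0 for 12CS_044. Below 0.3 CPM in 12CS_051 and above 1 CPM in both other genotypes were 85 genes, and 10 genes were below 0.3 CPM in both lines and above 1 CPM in Fleur11. Of the 99 genes, 11 had no counts at all in 12CS_051, and of the 18 genes, 7 had none in 12CS_044. Called against Fleur11 in the same direction at all 3 days were 165 higher and 873 lower genes in 12CS_051, and 83 higher and 202 lower genes in 12CS_044. With the compared libraries alone they were 6 and 92 in 12CS_051 and 30 and 105 in 12CS_044, and without Fleur11 at 12 dpi replicate 1 202 and 494, and 225 and 408. Leaving out 12CS_051 at 12 dpi replicate 1 or 2 gave 102 and 344 or 116 and 378 in 12CS_051, and leaving out Fleur11 at 12 dpi replicate 2 gave 230 and 1370.0. In 12CS_044 the number higher was 35 to 55 without any single library of Fleur11 or 12CS_044 at 0 dpi, and the number lower 128 and 134 without 12CS_044 at 21 dpi replicates 3 and 4. In 27 of 27 libraries, the markers of the labelled genotype, taken from the other days, were detected more often than those of either other genotype.

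In 12CS_051 at 21 dpi replicate 1, 701 genes had counts in that library alone, and by a separate rule 3 genes exceeded 1 CPM there with all other libraries below 0.1 CPM. In Fleur11 at 12 dpi replicate 1, 2554 genes had counts in that library alone. The other libraries had at most 229 such genes.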
